A study of Mus musculus with 4 samples.

How the data were processed

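RNA sequencing libraries of mammary glands from female MMTV-PyMT mice were analysed, 2 from control mice and 2 from mice with a miR-9 knockout. Per the labels' protocols, RNA was taken from glands at the hyperplastic stage with a Trizol reagent, libraries were made with the Illumina TruSeq RNA kit, and sequencing was done on an Illumina NovaSeq instrument. Bowtie 0.12.2 and the genome builds hg38, GRCm38 and mm10 are named in the submitters' processing notes with no role given. The counting tool, its strand setting and the size-factor method were not given in the sources used here. Of the 25806 listed gene identifiers, 25795 were found in the GENCODE M21 annotation of GRCm38, and 97.1% of these had the same coordinates there, so coordinates are those of the files on GRCm38.

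The deposited values were a normalised signal, per the files' own values: read counts per gene divided by 1 factor per library. In each library 100% of the values were whole multiples of the smallest value, within a tolerance of 1e-06 of that step. The steps were 1.0274 and 0.9964 in control libraries 1 and 2, and 0.9949 and 0.9712 in knockout libraries 1 and 2. They differed by 0.000% from the inverse of median-ratio size factors computed over the 4 libraries from those multiples. In all 4 libraries these values are those of read counts with 1 step per read. The general rule applied for accepting recovered reads nevertheless excludes steps near 1, to guard against rounded values, and it excluded control library 2 and knockout library 1. Because of that rule, not of the values themselves, no count-based test was run, and the values were tested on a log scale, as had been fixed for normalised values. Genes at 0 in every library were not listed. Such scaling sets the typical gene to no change, so fold changes are relative to the median gene, and a change in the RNA content of all cells cannot be seen.

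The values summed to 16378833 and 16418668 in control libraries 1 and 2 and to 15904798 and 16073229 in knockout libraries 1 and 2. These are sums of scaled values, which the scaling itself brings closer together, and the sums in steps were 15941909, 16478545, 15986996 and 16549344 in the same order. Genes above 0 numbered 22760 and 22427 in the controls and 23319 and 23263 in the knockouts, so detection differed between the groups, and no counting intervals were computed. A gene was tested if its value was at least 1 in at least 2 libraries, which left 22455 genes. Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3 (trend and robust settings, genotype as the only term, 2 residual degrees of freedom per gene before moderation), with Benjamini-Hochberg adjustment and an adjusted p threshold of 0.05. Fold changes are knockout minus control on that log2 scale, which understates the change of low genes. An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.33, so significance came from the fit across all genes. The labels do not say whether each library came from a separate animal, so p-values measure only the spread between these samples, which may be technical.

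Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 39 lists, with an estimated correlation and fry as alternatives. With an estimated correlation, camera judges a list on the 2 residual degrees of freedom. Hardly any list could pass it after adjustment, so failing it counts neither for nor against a list. The lists held 675 symbols for cell types, pathways and described miR-9 targets, and 658 of the symbols were matched. Seed sites of miR-9-5p were sought in the longest 3' UTR of each protein-coding gene, taken from the annotation as the exon bases after the stop codon. Genes with the 8mer site ACCAAAGA were compared with genes that had no 7mer or 8mer site in 10 bins of 3' UTR length, and the same was done for 74 scrambled sites of the same composition. The camera test of the site genes was against all other tested genes with a 3' UTR, without matching length. The test, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except the limma fit with voom weights, which was added afterwards.

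Named genes were chosen by rule: any row of a miR-9 gene or host transcript, the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 5e-06 of the library total and both knockout libraries on one side of both controls, leaving out clone-named and predicted symbols, and the 3 members of each described list with the smallest unadjusted p. Other names are stated as chosen after their values were seen. The procedure was tested on simulated data made from these libraries' means for this comparison, with 22703 genes and 1 dispersion of 0.007 for all genes. It recovered 90% of 100 genes changed 2-fold and 100% of 100 genes changed 4-fold. There were 7 false calls among 205, where calls of genes in a shifted list counted as true. The shifted list was called, and so were 0 of 38 null lists. Genes were drawn independently and null lists at random, so this does not test lists whose genes move together. Real genes vary unequally, so recovery in the libraries can be lower.

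The alternatives were quantile normalisation, no filter, a mean of at least 5, a pseudocount of 0.1, a replicate block, each library left out in turn, voom weights and an absolute log2 fold change of at least 1. The files held no fold changes or p-values of the authors, so no comparison with them was made. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.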

Results

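Messenger RNA was profiled in mammary glands of female MMTV-PyMT mice, in which the promoter of the mouse mammary tumour virus drives the polyomavirus middle T antigen in mammary epithelium, so that hyperplasia precedes carcinoma. Glands were collected at the hyperplastic stage, from mice of a mixed strain background derived from C57BL/6. There were 2 libraries from littermate controls and 2 from mice with a knockout of exon 1 of miR-9, a microRNA that represses messages carrying its seed site. The labels do not say which of the 3 miR-9 genes was deleted, or whether the knockout mice were homozygous. The comparison asks which messages differ between hyperplastic glands of mice with and without this knockout. The level of miR-9 itself was not measured here. Normalised read counts summed to between 15904798 and 16418668 per library over 25806 genes, of which 22427 to 23319 were above 0 in a library. Across genes, the log2 values of the controls correlated at r = 0.973 and those of the knockouts at r = 0.978, while control 1 correlated with knockouts 1 and 2 at 0.971 and 0.972, about as highly as with control 2. Control 2 stood apart, with 0.953 and 0.960 to knockouts 1 and 2. Values below are means ± SD of n = 2 libraries per group.

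The 3 miR-9 hairpins, Mir9-1 (GRCm38 chromosome 3, 88215598 to 88215686), Mir9-2 (chromosome 13, 83738814 to 83738885) and Mir9-3 (chromosome 7, 79505264 to 79505353), were not analysed here. The long non-coding RNA C130071C03Rik (ENSMUSG00000050334, chromosome 13, 83721381 to 83884194) carries Mir9-2 within an exon. Its normalised read count was 37.0 and 78.7 in the controls and 11.9 and 35.9 in the knockouts, and its log2 fold change of -1.33 (SE 0.60) did not pass the limma threshold (adjusted p = 0.292). Gm3764 (chromosome 3, 88206813 to 88229959), which holds Mir9-1 in an intron and was chosen by its position after the values were seen, lay near the floor at 1.03 and 2.99 in the controls and 3.98 and 3.89 in the knockouts (limma adjusted p = 0.611). Neither value checks the deletion itself.

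The knockout glands had higher messages of hormone receptor genes, MHC class II genes and antibody genes, and lower messages of the immediate-early genes Fos and Fosb and of the secreted matrix protein osteopontin. The progesterone receptor gene Pgr (ENSMUSG00000031870, chromosome 9, 8899833 to 8968611) was 10.2-fold higher, at 55.3 ± 10.5 in controls and 566 ± 21.7 in knockouts, a log2 fold change of 3.34 (SE 0.23, limma adjusted p = 0.00522). Slc5a5, the sodium-iodide symporter, rose by 3.08 on the log2 scale (SE 0.20) from 99.9 ± 18.6 to 849 ± 71.4, and Cited1, a transcriptional co-regulator, rose by 2.87 (SE 0.21) from 302 ± 98.1 to 2149 ± 61.5. The highest rise among the named genes was that of Bcan, which encodes the brain proteoglycan brevican (chromosome 3, 87987531 to 88000230), with 28.8 and 5.98 in the controls and 624 and 580 in the knockouts, a log2 fold change of 5.39 (SE 0.67, limma adjusted p = 0.0473). The other large rises among the named genes were those of Cyp3a57, Prol1, Cmtm5, Igkv1-117, Gjc3, Cxcl15, Itih2 and Fxyd2, with log2 fold changes from 2.92 for Fxyd2 to 4.88 for Cyp3a57. Cyp3a57 and the antibody segment Igkv1-117 belong to families of near-identical genes, so the split of reads between copies is uncertain. Without knockout 1 or knockout 2 the log2 fold change of Pgr was 3.38 and 3.31, with limma adjusted p = 0.732 and 0.551 where other settings gave at most 0.0197. Without control 1 or control 2 the log2 fold change of Bcan was 6.43 and 4.34, and its limma adjusted p over all settings ran from 6.1e-04 to 0.732.

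Spp1, which encodes osteopontin (chromosome 5, 104435118 to 104441050), fell from 40662 ± 3300 to 14987 ± 181, a log2 fold change of -1.44 (SE 0.10, limma adjusted p = 0.00522). Among the named genes the largest falls were those of the chitinase gene Chit1 with a log2 fold change of -2.47 (SE 0.27) and of Fosb with -2.37 (SE 0.30). Ptgs2, the inducible prostaglandin synthase, fell by 1.90 on the log2 scale, Fos by 1.88, and Cyr61, a matricellular gene, by 1.85. Tenascin C (Tnc) fell from 766 ± 87.1 to 254 ± 14.8, and Pglyrp1, the imprinted gene Peg3, Ier3, Akap12 and Il20rb fell by 1.46, 1.44, 1.42, 1.37 and 1.25 on the log2 scale. Spp1 had -1.43 without knockout 1 and -1.45 without knockout 2 (limma adjusted p = 0.732 and 0.551), and Ptgs2, Pglyrp1 and Il20rb no longer passed without control 2.

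**Figure D1:**
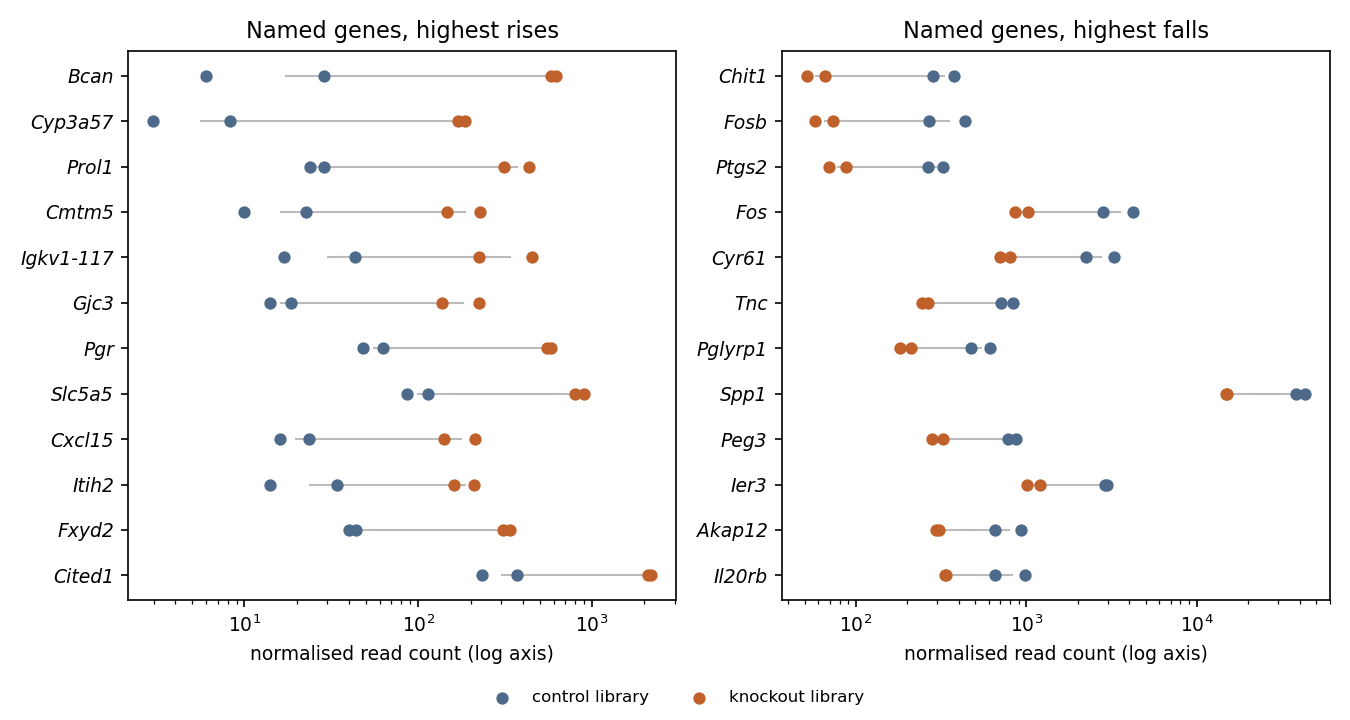
Normalised read count on a log axis of the 12 named genes with the highest rises (left) and the 12 with the highest falls (right) in each of the 2 control and 2 knockout libraries, after the abundance and symbol filters that removed, for example, Capn11 at -5.17 (log2) and Klb at 4.65, both chosen after their values were seen. Each point is a library and each line joins the group means, and in every row both knockout libraries lie on one side of both controls.

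Over all 22455 genes tested, 131 passed limma's adjusted p of 0.05, 93 higher and 38 lower in the knockouts, and 112 of the 131 were protein-coding. In all 131 both knockout libraries lay on one side of both controls, as they did in 51.2% of all tested genes, where chance gives 16.7% in each direction. The count depended strongly on single libraries: 0 genes passed in limma without knockout 1 (1384 at an unadjusted p under 0.05) or without knockout 2 (1805), while 2361 passed without control 1 and 173 without control 2, with the lone library assumed to vary like the other group. It was 257 with quantile normalisation, 332 with no filter and 33 with a pseudocount of 0.1, at which Bcan, Cmtm5, Igkv1-117, Cxcl15, Itih2, Fosb, Ptgs2, Pglyrp1, Akap12 and Il20rb were among 23 named genes that no longer passed.

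**Figure D2:**
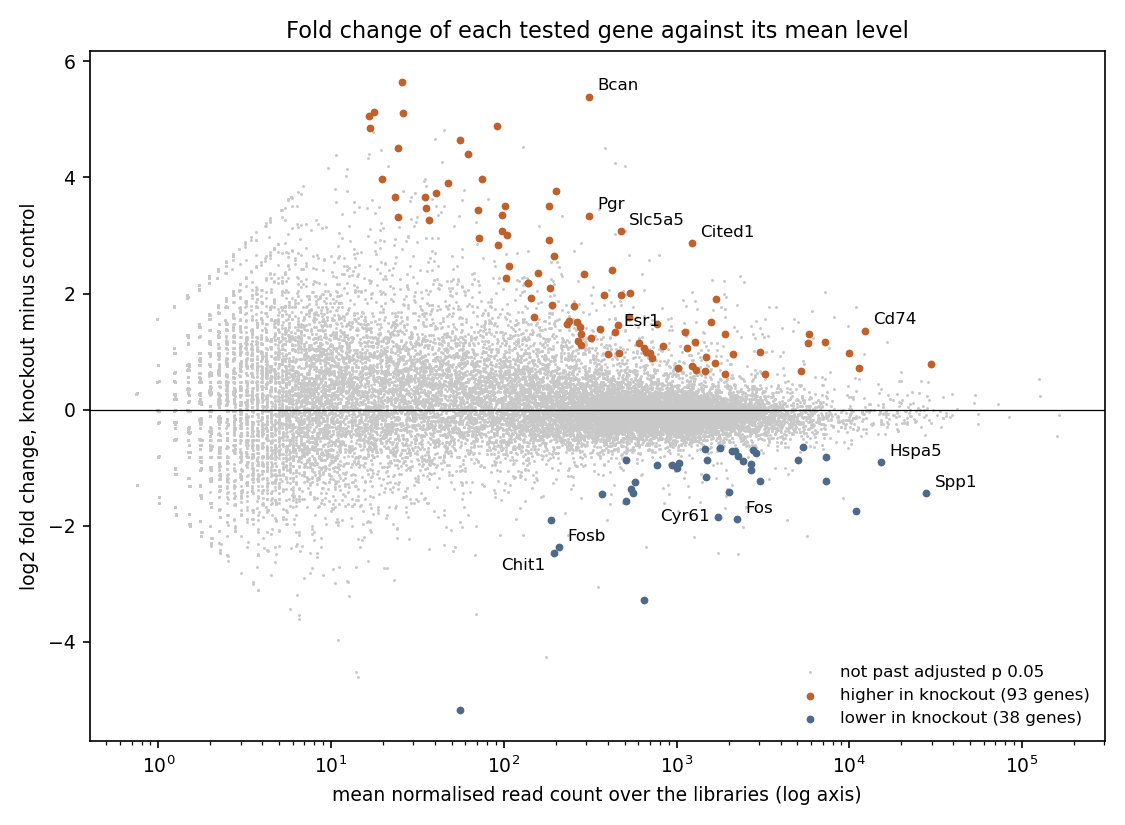
Log2 fold change (knockout minus control) of each of the 22455 tested genes against its mean normalised read count over the 4 libraries, on a log axis. The 93 genes higher and the 38 lower in the knockouts past adjusted p 0.05 are coloured, and named points such as Pgr at 3.34 and Spp1 at -1.44 are in the text.

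Genes of hormone-sensing luminal cells, the epithelial cells that carry estrogen and progesterone receptors, were higher in the knockouts. Of 14 tested members, Pgr, Cited1 and the estrogen receptor gene Esr1 rose over all genes tested. Adjusted over the list alone, 12 rose and 1 fell, Xbp1 with a log2 fold change of -0.36, named here after its value was seen. Esr1 rose from 251 ± 26.9 to 633 ± 21.2, a log2 fold change of 1.33 (SE 0.16, limma adjusted p = 0.0208). The quartiles of the list's log2 fold changes were 1.27 and 1.85 and its camera adjusted p was 6.9e-09, with adjusted p = 0.628 with an estimated correlation. Without either knockout library no gene of the list passed in limma, and without control 1 there were 9. General luminal epithelium genes went the other way, with a median of -0.24 over 23 genes (camera adjusted p = 1.2e-04, adjusted p = 0.628 with an estimated correlation). Adjusted over the list alone, 10 of them fell and 2 rose, and over all genes only the keratin gene Krt19 passed, higher by 0.98 (SE 0.14), which ended without control 2 at 0.81 (limma adjusted p = 0.0778). Without control 1, 2 genes of the list passed higher and 7 lower in limma, and with no filter 1 passed higher and 2 lower. The claudin genes Cldn7 and Cldn4 had log2 fold changes of -0.61 and -0.56 (limma adjusted p = 0.0552 and 0.0661).

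MHC class II genes, which present antigen to helper T cells, were higher in the knockouts. Within the list of dendritic cell and MHC class II genes, 5 of 14 rose over all genes tested, and adjusted over the list alone 9 did. The invariant chain gene Cd74 rose from 6930 ± 561 to 17780 ± 149, a log2 fold change of 1.36 (SE 0.10, limma adjusted p = 0.00538). H2-Eb1 rose by 1.30 and H2-Aa by 1.16 on the log2 scale, and H2-Ab1 and the class II transactivator Ciita, named here after their values were seen, rose by 1.14 and 1.12. Without knockout 1 or knockout 2, Cd74 had 1.35 and 1.37 (limma adjusted p = 0.732 and 0.551), and no gene of the list passed. There were 10 without control 1, and with a pseudocount of 0.1 only Cd74 passed, H2-Aa and H2-Eb1 having limma adjusted p = 0.0567 and 0.0605. The list's median was 1.13 (camera adjusted p = 1.7e-09, adjusted p = 0.628 with an estimated correlation).

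Lists of lymphocytes and blood were also higher. For B and plasma cells the median was 2.03 over 17 genes (camera adjusted p = 1.8e-07, adjusted p = 0.628 with an estimated correlation). The B-cell coactivator Pou2af1 rose over all genes tested, by 2.09 (SE 0.31), and 9 genes did so adjusted over the list alone, while Ighm and Cd79b had log2 fold changes of 1.85 and 2.64 (limma adjusted p = 0.0735 and 0.108). This list differed most between the knockouts, with a mean centred log2 level of 2.30 in knockout 1 and -0.06 in knockout 2, against -0.80 and -1.45 in controls 1 and 2, and its median was 1.42 without knockout 1. Without control 1, 5 genes of the list passed in limma, and with a pseudocount of 0.1 Pou2af1 did not (limma adjusted p = 0.0806). For T and NK cells the median was 1.17 over 24 genes (camera adjusted p = 5.7e-07, adjusted p = 0.628 with an estimated correlation), with 0 past the threshold in limma over all genes (12 at an unadjusted p under 0.05) and 5 adjusted over the list alone. Il2rb, Zap70 and Cd3g had log2 fold changes of 1.67, 1.89 and 1.41, and 4 genes of the list passed without control 1. Of 5 erythroid genes, the haemoglobin genes Hba-a1 and Hbb-bs rose by 1.48 and 1.34 on the log2 scale, with near-identical copies that leave the split of reads uncertain, and Hbb-bt had 1.17, while Hbb-bs did not pass with a pseudocount of 0.1 (list median 1.17, camera adjusted p = 1.2e-04, adjusted p = 0.628 with an estimated correlation).

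Immediate-early genes, which cells switch on within minutes of a stimulus, were lower in the knockouts. Of 18 members, 6 fell over all genes tested (Fos, Fosb, Ier3, Zfp36, Ier2 and Junb) and 12 adjusted over the list alone. Junb is named here after its value was seen. Ier3 fell from 2937 ± 60.1 to 1105 ± 146 (limma adjusted p = 0.00614), Zfp36 by 1.16 on the log2 scale and Ier2 by 0.93. The median was -0.63 (camera adjusted p = 1.1e-10, adjusted p = 0.628 with an estimated correlation). Genes of the unfolded protein response, chaperones and foldases of the endoplasmic reticulum, were lower as well, with a median of -0.56 over 19 genes (camera adjusted p = 7.6e-11, adjusted p = 0.628 with an estimated correlation). The chaperone gene Hspa5 fell from 19997 ± 2025 to 10685 ± 558, a log2 fold change of -0.90 (SE 0.11, limma adjusted p = 0.0209). Pdia6, Creld2 and Manf, the last named here after its value was seen, fell by 0.81, 0.96 and 1.04. Adjusted over the list alone, 14 fell. With a pseudocount of 0.1 3 immediate-early and no unfolded-protein genes passed, and without control 2 only Creld2 of the 4 unfolded-protein genes did, with Hspa5, Pdia6 and Manf no longer past. The limma adjusted p of Hspa5 ran from 0.00679 with no filter to 0.732 without knockout 1. Without either knockout library no gene of either list passed in limma, and without control 1 there were 11 of each.

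Lists of stromal cells, and of basal and Wnt-response genes, had higher medians in the knockouts, and in each of them control 2 was the lowest library. In mean centred log2 level, control 1 lay above knockout 2 for the endothelial (0.16 against 0.07) and fibroblast (0.14 against 0.03) lists. In the others both knockouts lay above both controls. Singly, 4 of 18 endothelial and 9 of 24 fibroblast genes had both knockouts above both controls. The adipocyte list had a median of 1.00 over 23 genes (camera adjusted p = 1.8e-07, adjusted p = 0.628 with an estimated correlation), with 0 genes past the threshold in limma over all genes or adjusted over the list alone (9 at an unadjusted p under 0.05). Aqp7, Gpd1 and Pnpla2 had log2 fold changes of 2.25, 0.82 and 0.52. Its mean centred level was 1.23 in knockout 1, 0.01 in knockout 2, -0.22 in control 1 and -1.02 in control 2. The median was 0.53 without knockout 1 and 1.76 without knockout 2, and 3 of its genes passed in limma without control 1. The mesenchymal transition list had a median of 0.78 (camera adjusted p = 2.3e-04, adjusted p = 0.628 with an estimated correlation; 6 genes higher adjusted over the list alone), with Vim at 1.60, Twist1 at 1.51 and Zeb2 at 1.02. The endothelial list had a median of 0.62 (camera adjusted p = 5.8e-04, adjusted p = 0.628 with an estimated correlation), with Vwf at 1.06, Eng at 0.85 and Cldn5 at 1.20, and the fibroblast list a median of 0.68 (camera adjusted p = 0.0011, adjusted p = 0.628 with an estimated correlation), in which Tnc fell and Fbln1 and Dcn had 1.22 and 1.01. Without control 2 the endothelial and fibroblast medians were 0.09 and 0.15 (camera adjusted p = 0.176 and 0.0867), and without knockout 1 they were 0.37 and 0.42 (camera adjusted p = 0.0317 and 0.0589). Without control 1 they were 1.12 and 1.23. The mesenchymal median was 0.40 without control 2 and 1.20 without control 1. Basal and myoepithelial genes had a median of 0.50 (camera adjusted p = 0.00318, adjusted p = 0.628 with an estimated correlation), with Pdpn at 0.90, Trp63 at 0.50 and Krt14 at -0.46, and Schwann cell and nerve genes one of 0.59 (camera adjusted p = 5.8e-04, adjusted p = 0.628 with an estimated correlation), with S100b at 1.06, Ngfr at 2.09 and Pmp22 at 0.49. Wnt-response genes had a median of 0.77 (camera adjusted p = 2.8e-04, adjusted p = 0.628 with an estimated correlation), with Wif1 at 1.43, Sfrp2 at 1.22 and Axin2 at 1.61. Without control 2 the Wnt median was 0.41, and without control 1 the Wnt and basal medians were 1.17 and 0.98. Without control 1, 9 mesenchymal, 10 Wnt-response, 6 endothelial, 15 fibroblast, 6 basal and 3 Schwann cell genes passed higher in limma. Except for Tnc none of the genes named here passed over all genes. Adjusted over the list alone, 4 Schwann cell genes and 4 Wnt-response genes were higher, and 2 basal genes were higher and 1 lower.

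**Figure D3:**
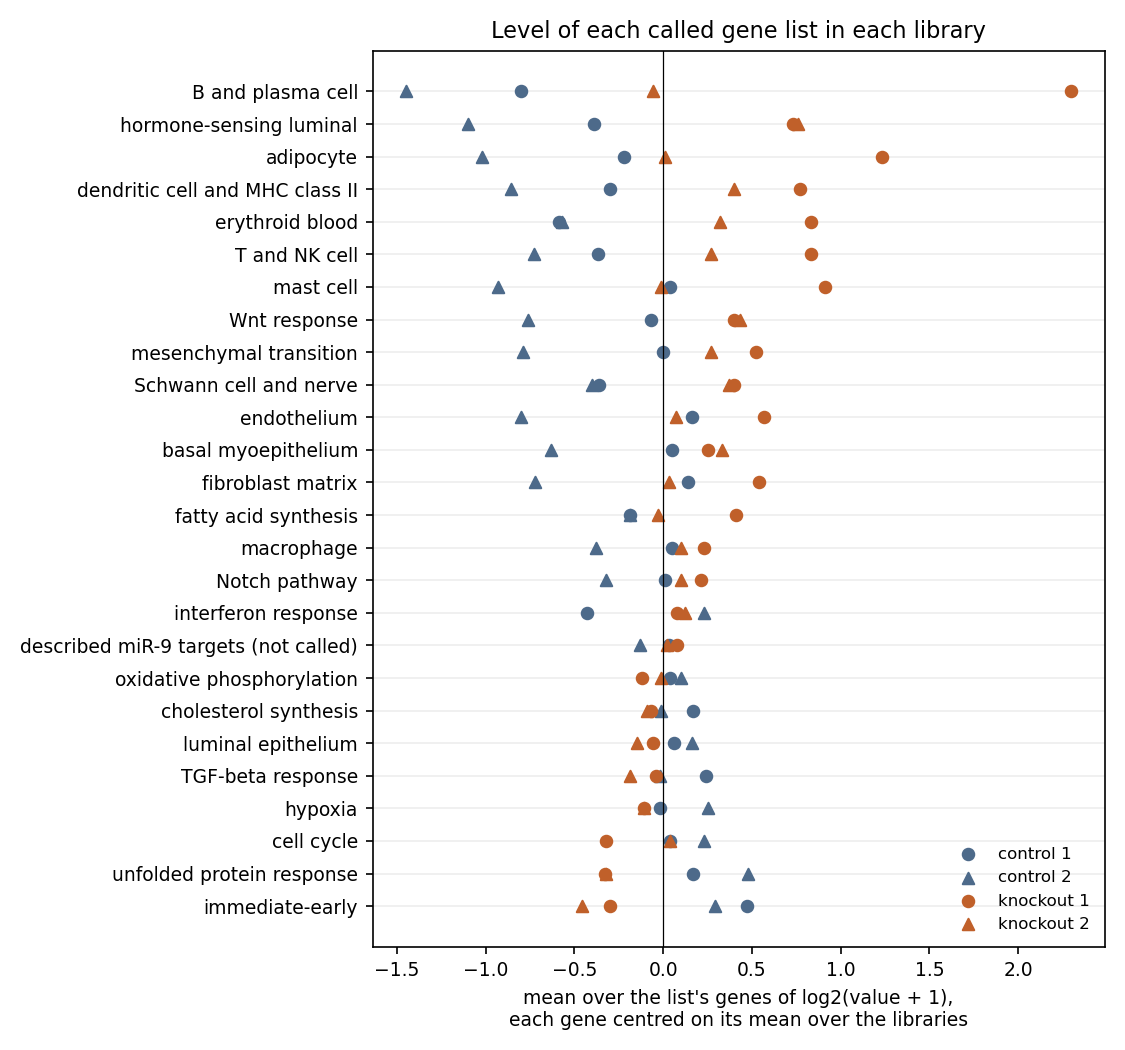
Mean over each list's genes of log2(value + 1), each gene centred on its mean over the 4 libraries, for the 25 called gene lists and the described miR-9 targets in control libraries 1 and 2 and knockout libraries 1 and 2. The hormone-sensing list lies at 0.73 and 0.76 in the knockouts and at -0.39 and -1.10 in the controls, and the B and plasma cell list spreads from -0.06 to 2.30 in the knockouts.

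Further lists were called as well. Cell cycle genes had a median of -0.30 over 30 genes (camera adjusted p = 1.8e-04, adjusted p = 0.628 with an estimated correlation), with Birc5 at -0.74, Mki67 at -0.64 and Mcm6 at 0.56, and without knockout 1 this was -0.11 (camera adjusted p = 0.145), and without knockout 2 it was -0.49. Cholesterol synthesis genes had a median of -0.22 (camera adjusted p = 0.00471, adjusted p = 0.628 with an estimated correlation), with Dhcr7 at -0.61, Hmgcs1 at -0.50 and Sqle at -0.37, and without control 1 this was -0.08 (camera adjusted p = 0.323), and without control 2 it was -0.37. Oxidative phosphorylation genes had a median of -0.15 (camera adjusted p = 0.00471, adjusted p = 0.628 with an estimated correlation), which was -0.10 without knockout 1 (camera adjusted p = 0.109), -0.08 without control 2 and -0.09 with quantile normalisation (camera adjusted p = 0.277). Macrophage genes had a median of 0.42 (camera adjusted p = 0.0134, adjusted p = 0.628 with an estimated correlation), in which Spp1 fell and Csf1r and C1qb had 0.91 and 0.53, and without control 2 the median was 0.23 (camera adjusted p = 0.0808). Interferon-response genes had a median of 0.23 (camera adjusted p = 0.0134, adjusted p = 0.736 with an estimated correlation), with the chemokine gene Cxcl9 higher by 1.60 (SE 0.24) but not past the threshold with a pseudocount of 0.1, and without control 1 the median was -0.02 (camera adjusted p = 0.138), and without control 2 it was 0.48. Fatty acid synthesis, Notch and mast cell genes had medians of 0.29, 0.41 and 0.97 (camera adjusted p = 0.00797, 0.0292 and 0.0447, each with adjusted p = 0.628 with an estimated correlation). Hypoxia and TGF-beta response genes had -0.18 and -0.16 (camera adjusted p = 0.0292 and 0.0447, each with adjusted p = 0.628 with an estimated correlation), and Cyr61 of the latter fell. The fatty acid synthesis median was 0.12 without knockout 1 and 0.55 without knockout 2, that of Notch 0.25 without control 2 and that of hypoxia -0.08 without knockout 2. The mast cell median was 1.66 without control 1, 0.47 without control 2 and 1.48 without knockout 2, and 1.49 with a pseudocount of 0.1. The call of each of these 5 lists ended without at least 1 of the libraries. In all, camera called 25 of 39 lists, 17 higher and 8 lower. With an estimated correlation 0 passed (1 at an unadjusted p under 0.05), but with 2 residual degrees of freedom that setting could hardly call a list. In fry 0 passed for a shift in 1 direction (7 at an unadjusted p under 0.05).

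The lists that were not called had medians of -0.60 for skeletal muscle, -0.07 for ribosomal proteins, -0.23 for milk and secretion, 0.42 for brown fat, 0.48 for angiogenesis, -0.07 for glycolysis, -0.03 for the FoxO response, 0.17 for genes encoded in mitochondria, 0.29 for neutrophils, 0.03 for fatty acid oxidation, 0.15 for NF-kB inflammation, -0.00 for skin keratinocytes and -0.05 for stemness. With each library left out in turn, the medians ran from -0.99 to 0.07 for skeletal muscle, from -0.12 to -0.02 for ribosomal proteins, from -0.32 to -0.01 for milk and from 0.24 to 1.07 for brown fat. They ran from 0.15 to 0.77 for angiogenesis, from -0.20 to 0.05 for glycolysis, from -0.10 to 0.05 for the FoxO response and from -0.06 to 0.45 for genes encoded in mitochondria. For neutrophils the range was -0.04 to 0.70, for fatty acid oxidation -0.09 to 0.11, for NF-kB inflammation -0.07 to 0.28, for skin -0.07 to 0.57 and for stemness -0.07 to -0.02. With quantile normalisation brown fat had 0.13, neutrophils 0.02, NF-kB inflammation 0.09, glycolysis -0.02, the FoxO response -0.01 and skin -0.22. Several calls depended on single libraries: without control 1 camera called angiogenesis (0.77), brown fat (0.84), glycolysis (-0.20) and genes encoded in mitochondria (0.45), with adjusted p = 0.0115, 0.0414, 0.00948 and 0.0474. Without control 2 it called skeletal muscle (-0.99, adjusted p = 9.9e-05) and ribosomal proteins (-0.09, adjusted p = 0.00791), without knockout 1 genes encoded in mitochondria (0.44, adjusted p = 0.00596), and without knockout 2 milk (-0.23), ribosomal proteins (-0.12), brown fat (1.07) and angiogenesis (0.61), with adjusted p = 0.0107, 0.0185, 0.0206 and 0.021. Skeletal muscle also passed with quantile normalisation (-0.78, camera adjusted p = 0.0178) and with no filter (-0.67, camera adjusted p = 0.0291), and ribosomal proteins with no filter (camera adjusted p = 0.0485). Single members passed limma's threshold in some of them. Btn1a1, a milk-fat globule gene, rose by 1.06, Pfkfb3, a regulator of glycolysis, by 0.97 and the aldehyde dehydrogenase gene Aldh1a1 by 2.33, and Ptgs2 fell. With a pseudocount of 0.1 none of these 4 passed, and without control 2 Pfkfb3 and Ptgs2 did not. Median and mean differed in sign for stemness (mean 0.14), NF-kB inflammation (mean -0.11), skin keratinocytes (mean 0.21) and the described miR-9 targets below (mean 0.10), and for fatty acid oxidation the test went lower while the median was higher.

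Described miR-9 targets showed no common shift. Of 28 tested, 0 passed in limma over all genes or adjusted over the list alone (7 at an unadjusted p under 0.05), the median log2 fold change was -0.00, and the knockouts were both above both controls for 8 genes and both below for 10 (camera adjusted p = 0.939). Stard13, Tgfbr2 and Lifr had log2 fold changes of 0.93, 0.49 and 0.45 (limma adjusted p = 0.132, 0.133 and 0.152). Without control 1, 5 of the targets passed higher and 2 lower. The wider set was 707 tested genes with an 8mer seed site of miR-9-5p in the 3' UTR. Their median was 0.034 higher on the log2 scale than that of genes of like 3' UTR length with no site. Camera instead compared the 707 with all other tested genes that had a 3' UTR, without matching length. It did not pass (camera p = 0.253, p = 0.324 with an estimated correlation). Of 74 scrambled sites, 27 gave a shift at least as high, and their shifts ran from -0.046 to 0.082. Of the 131 genes past the threshold, 4 had an 8mer site, named here after their values were seen. Pgr and the sorting receptor gene Sorl1, with a log2 fold change of 0.62, rose, and Tnc and the kinesin gene Kif2a, with -0.86, fell.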

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

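The fit with voom weights was chosen only after the data were examined. The 131 genes past the threshold became 257 with quantile normalisation, 332 with no filter, 367 with a replicate block and 33 with a pseudocount of 0.1, and stayed within 1.5 times at 90 with a mean of at least 5, 182 with voom weights (118 of them shared) and 93 with an absolute log2 fold change of at least 1. Leaving out a library gave from 0 genes (without knockout 1 or knockout 2) to 2361 (without control 1), and 173 without control 2, of which 88 were shared. The construction of these fits shows part of the cause: without a knockout library the spread comes from the controls alone (r = 0.973 across genes), and without a control from the knockouts alone (r = 0.978). All 131 genes kept their direction in each setting that tested them, 127 of 127 without a knockout library. With a library left out this was fixed in advance and is no sign of stability. In all 131 both knockout libraries lay on one side of both controls. Of 41 named genes past the threshold, 41 still passed with quantile normalisation, no filter, the block and without control 1, 39 with voom weights, 34 with a mean of at least 5, 33 without control 2 (the others were Igkv1-117, Ptgs2, Pglyrp1, Il20rb, Pfkfb3, Krt19, Hspa5 and Pdia6), 18 with a pseudocount of 0.1 and 0 without either knockout.

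The 25 lists called became 0 with an estimated correlation and 0 in fry, whose lowest adjusted p was 0.178, while 14 lists passed fry's test of change in either direction. With an estimated correlation, camera judges a list on 2 residual degrees of freedom, so hardly any list could pass. The Schwann cell list had an estimated correlation of 0.00, yet its camera adjusted p went from 5.8e-04 to 0.628. For that list, correlation between genes was therefore not the cause. Failing this setting counts neither for nor against a called list. For fry the cause was not tested. With other settings 22 to 27 lists passed, and from 20 to 27 with a library left out. The interferon-response list reversed to a median of -0.02 without control 1 and had 0.48 without control 2. The seed-site shift lay between 0.016 and 0.039 with a library left out and at 0.040 with quantile normalisation, 0.041 for the wider 7mer or 8mer site and 0.026 for the median scrambled site, and passed under none of them (camera p from 0.0988 to 0.445). As to pairing, same-numbered libraries deviated together at r = 0.24 across 13782 genes, but 2 pairs and the labels do not establish that numbers mark litters, so the replicate block (367 genes, 24 lists; 12 adipocyte and 6 fibroblast genes higher) is given only here. Planned count-model alternatives were not run, because the rule applied for accepting recovered reads excludes steps near 1, as 2 libraries have, although the steps of all 4 matched read counts divided by size factors. Depth of 15904798 to 16418668 normalised reads per library leaves genes with a few reads, such as Gm3764, undecided.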

Other observations

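The counts of antibody segments and of genes near the miR-9 loci, the test of epithelial share and both tests of the MHC class II genes were chosen only after the results were seen.

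Antibody gene segments were higher in the knockouts as a class. Of 147 tested immunoglobulin variable segments, 100 had both knockout libraries above both controls (68.0%, against 25.5% of all tested genes and 16.7% by chance). Both lay below for 2, and 10 passed limma's threshold, all higher. Segments can rise together within a library, so the 147 are not independent trials and these shares are no test. All 11 tested constant genes were above in both knockouts, and Ighg1 and Ighg2c passed, with log2 fold changes of 2.40 and 2.01. Summed normalised read counts of the constant genes were 11339 and 6232 in the controls and 42750 and 22430 in the knockouts. Segments share near-identical sequence, so single segments are uncertain while their sum is less so. Of 7 T-cell receptor constant genes, 6 were above in both knockouts, but of 6 T-cell receptor variable segments 1 was (16.7%, the chance share), and none of either kind passed in limma.

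Bcan, the gene with the highest rise among those named, lies 215 kb from Mir9-1. Within 1000 kb of Mir9-1, 78 genes were tested and Bcan alone passed, where the share over all genes would give 0.46. In limma 25 of the 78 had an unadjusted p under 0.05, a larger share than the 4040 of 22455 over all genes. An absolute log2 fold change of at least 1 was seen for 7 of them, against 10 of 56 around Mir9-3. The genes beside Bcan, Hapln2 and Nes, had log2 fold changes of -0.37 and 0.02, and the median over the window around Mir9-1 was -0.07. Around Mir9-2 limma called 0 of 6 genes (1 at an unadjusted p under 0.05), and around Mir9-3 0 of 56 (8 at an unadjusted p under 0.05). The labels do not say which locus was deleted.

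Outside the lists, the non-coding RNA Gm26917 took 0.091% and 0.116% of the control totals and 0.035% and 0.028% of the knockout totals (log2 fold change -1.75, limma adjusted p = 0.00814). Capn11 had 63.7 and 156 in the controls and 2.99 and 0.971 in the knockouts (log2 fold change -5.17, limma adjusted p = 0.0208). Both were picked after their values were seen.

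Hormone-sensing luminal genes were higher in both knockout libraries. A larger luminal share in the knockout libraries is argued against by the general luminal list, whose median was -0.24, by a bound set after the results were seen. Krt19 of that list nevertheless rose by 0.98. The basal and myoepithelial list had a median of 0.50, so a larger share of the epithelium as a whole was not settled. A larger share of hormone-sensing cells with unchanged expression per cell would lift alike only those members that these cells alone express. How far each member is also expressed elsewhere was not measured. The members' log2 fold changes ran from -0.36 to 3.34 with an interquartile range of 0.58, between the bounds set for either outcome. The lowest, Xbp1, is also in the unfolded-protein list. More cells and more message per cell therefore cannot be told apart. The genotype may underlie the rise, and the stage of the estrous cycle at collection, which the labels do not give, stays open and untested.

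MHC class II genes were higher in both knockout libraries. B cells as the only source of the rise are argued against by the knockout libraries. Between these the 5 genes Cd74, H2-Aa, H2-Ab1, H2-Eb1 and Ciita differed by a median of 0.02 (log2, from -0.08 to 0.23) where the B-cell list differed by 1.71. Between controls 1 and 2, H2-Eb1 (3974 and 2851), H2-Aa (5075 and 3896) and H2-Ab1 (4032 and 3169) fell, as did the B-cell list (mean centred level -0.80 and -1.45). Cd74 (7326 and 6533) and Ciita (178 and 172) differed less there, so B cells as part of the source stay open. A smaller epithelial share raising other cell types alike cannot be told apart from a rise of its own, because the dendritic and MHC class II list exceeded the macrophage list by 0.60 to 0.86 but the endothelial list by 0.14 to 0.91 over the pairs of a knockout and a control library. Against the T and NK list the excess was 0.01 to 0.21, and against the fibroblast list 0.06 to 0.89. The median log2 fold change of the T and NK list was 1.17, above the 1.13 of the dendritic and MHC class II list. Which of these lists rose more thus depended on the measure. The B-cell list exceeded the dendritic and MHC class II list in all 4 pairs, and the adipocyte list did so in at least 1. More dendritic cells, or induction in cells already present, may each be the source, and neither was tested apart from the genotype.

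Immediate-early and unfolded-protein genes were lower in both knockout libraries. A gene length trend between libraries is argued against, because the median of the 36 members went from -0.63 to -0.73 once the trend was removed, and a GC content trend likewise, with -0.74 afterwards, and both lists still passed. Time of day of collection cannot be told apart from genotype: evening-arm clock genes had a median of 0.26 and morning-arm genes 0.11, between the bounds set. Highest in the evening arm were Nr1d1 at 1.40, Per1 at 0.76 and Dbp at 0.72, and lowest were Per3 at -0.25 and Bhlhe41 at -0.05. Of the clock genes only Per1 passed (limma adjusted p = 0.03). The interval between death and freezing, which may also move immediate-early genes, is not given in the labels and stays untested.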
